A study of Mus musculus with 8 samples.

How the data were processed

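RNA was measured in tdTomato-marked cells sorted from the cerebral cortex of mice carrying a Cre driver under the parvalbumin locus and a red fluorescent reporter, with the DNA methyltransferase gene Dnmt1 either intact (WT) or flanked by recombination sites for deletion (KO). Per the labels, mice were 6 or 18 months old on a C57BL/6 background, the floxed Dnmt1 line came from a mixed B6;129Sv stock, tissue was dissociated with enzymes and by trituration, and total RNA was taken. The design text gives 4 groups (WT and KO at 6 and 18 months) with 2 technical replicates each, made from cells pooled from 6 WT and 6 KO mice. One hemisphere of each mouse went to RNA and the other to DNA. The DNA data were not analysed here. Whether the mice are counted per age, and whether the replicates are libraries, runs or cell pools, is not given in the sources used here. They were assumed to be 2 libraries of 1 pool per group. On that assumption the p-values of the group model measure the spread between libraries of the same pool, which may be technical, and not the spread between animals. The residual of the additive model also holds differences between pools that vary with age and genotype together.

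The deposited values were raw read counts per gene, 1 file per library, with 55573 Ensembl gene IDs each. Per the submitters' processing notes, the authors used CASAVA 1.8.2, STAR 2.5.2a and featureCounts 1.5.0-p1 with the mm10 build to make these counts. The annotation release and the settings for strand and for reads with several matches are not given in the sources used here. Values of near-identical copies (haemoglobin genes, Y RNAs, clustered protocadherins, mitochondrial and ribosomal RNA look-alikes) and of genes overlapping another one are accordingly uncertain. Gene symbols and positions were taken from a GENCODE annotation of the same build, which named 55394 of the IDs (99.7%); IDs without a symbol held at most 0.02% of the counts of a library.

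Library totals ranged from 6008175 to 13551218 counts. A group total of 0 reads was read as at most 3 reads over the group, and folds against such a group are given as lower bounds against that floor. For groups with 1 to 3 reads the ratio is given with an exact 95% binomial interval. Reads carry no molecular identifiers as far as the sources used here say, so floors and intervals cover counting error only.

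Differences were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and F test, TMM scaling, filterByExpr with a minimum count of 10), with Benjamini-Hochberg adjustment over the 18205 genes tested and a threshold of 0.05. The tested genes held at least 99.7% of the counts of each library. The 4 groups were fitted in 1 model so that they shared the estimate of the spread (common biological coefficient of variation 0.0539, 4 residual degrees of freedom, 19.1 prior degrees of freedom). The contrasts were KO against WT at 6 months, KO against WT at 18 months, 18 against 6 months in WT, 18 against 6 months in KO, and the interaction of genotype and age, which is the log2 fold change of KO against WT at 18 months minus that at 6 months. A further additive model of age and genotype gave KO against WT across both ages with 5 residual degrees of freedom. Levels are given as CPM, the deposited counts scaled to the TMM-adjusted totals of the tested genes, as mean ± SD over the 2 libraries of a group.

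Fixed before the data were examined were 15 lists of cell type markers and 20 other gene lists with 1031 entries in all. They were tested against all other genes with camera from limma 3.58.1 on voom-weighted log2 CPM with a preset correlation between genes of 0.01, adjusted over the 35 lists of a comparison; camera with an estimated correlation per list and fry were run beside it. Members of a list were also adjusted over the list alone.

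The genes named were set by a rule fixed at the same time. It took Dnmt1, Dnmt3a, Dnmt3b, Pvalb, Gad1 and Gad2 in every genotype comparison. For each pairwise comparison it took the 8 higher and the 8 lower genes with the largest fold among those past the threshold, with at least 10 CPM in the higher group, both libraries of one group above both of the other, and a symbol that is not a clone or pseudogene name. It took up to 4 members of each list with the smallest p, and for the interaction and the additive model the 5 genes with the smallest adjusted p in each direction. A list of 23 genes of the pituitary and the genes S100b, Apoe, Gh, Pou1f1, Tshb, Chga and Pcsk2 were chosen after values had been seen. A few of the genes taken are not reported here.

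Calls near the Dnmt1 locus were compared with calls elsewhere by a two-sided Fisher's exact test over the tested genes within 20 Mb. The pair of genotype comparisons share no library, nor do the pair of age comparisons, and their overlaps are set beside the number that independent lists of the same sizes would share. The method was tested on simulated data drawn from the real means and library sizes with 1.5-, 2- and 4-fold changes. For KO against WT at 6 months it recovered 49.3%, 74.6% and 83.3% of the changed genes with 7 false calls among 17669 genes; for KO against WT at 18 months 47.8%, 77.6% and 89.4% with 14 among 17668; for 18 against 6 months in WT 40.3%, 79.1% and 87.9% with 7 among 17670; and for 18 against 6 months in KO 43.3%, 67.2% and 92.4% with 14 among 17661. For the interaction it recovered 29.9%, 50.7% and 83.3% with 9 false calls among 17643 genes, and for the additive model 52.2%, 85.1% and 97% with 8 among 17680. The simulated libraries were drawn independently with the spread between libraries of a group, and few genes were changed. No difference between pools or animals was added, so these false calls do not cover such differences.

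Alternatives were relative log expression and upper-quartile scaling, no filter and a filter at 5 CPM in 2 libraries, limma-voom, DESeq2 1.42.0, the replicate number as a block, a 2-fold minimum, the 4 compared libraries alone, each library left out in turn, libraries summed to 4 pools, and other windows around Dnmt1. When a library was left out, its group kept a single library, which was assumed to vary like the other groups. Fits without rRNA-like genes and without both WT libraries of 6 months were added after the data had been seen. The plots were drawn with matplotlib 3.10.9 in Python 3.11.15.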

Results

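Gene expression was profiled by RNA-seq in 8 libraries from sorted, tdTomato-marked cortical cells of mice with intact (WT) or conditionally deleted (KO) Dnmt1, at 6 and 18 months of age, with 2 libraries per group. Dnmt1 encodes the methyltransferase that keeps DNA methylation through replication and is also expressed in neurons after division. Total counts were 6008175 and 6024905 in WT at 6 months, 8973571 and 8481613 in KO at 6 months, 8495242 and 13551218 in WT at 18 months, and 12489638 and 11092756 in KO at 18 months. Across genes, log2 CPM of the libraries of a group correlated with Pearson's r of 0.976 in WT and 0.989 in KO at 6 months, and 0.989 in WT and 0.992 in KO at 18 months. The chi-square statistic between the libraries of a group was between 2.72 and 5.37 per gene, so no pair was 1 library deposited again. WT at 6 months stood apart: its libraries correlated with those of other groups at 0.9 to 0.951, while libraries of the other 3 groups correlated with each other at 0.958 to 0.977.

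RNA composition differed with the groups too. The rRNA-like gene Gm26917 took 9.63% of counts in WT and 4.58% in KO at 6 months, against 2.88% in WT and 1.74% in KO at 18 months. The mitochondrial rRNA genes took 0.857% in WT and 5.24% in KO at 6 months, and 3.49% in WT and 1.99% in KO at 18 months. The nuclear RNA Malat1 took between 2.53% and 3.92% of counts in the group means.

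The cells were sorted as parvalbumin interneurons, and the first question was which cell types the RNA represented. Transcripts of glia were the most abundant of the marker lists in every library. The 16 oligodendrocyte markers summed to 15200 ± 12.7 CPM in WT and 33670 ± 715 CPM in KO at 6 months (SD, n = 2), and to 44850 ± 191 CPM in WT and 30820 ± 358 CPM in KO at 18 months. The 18 astrocyte markers summed to 15630 ± 6.57 and 9399 ± 73.9 CPM at 6 months and to 5932 ± 78 and 11250 ± 107 CPM at 18 months, in WT and KO. Markers of oligodendrocyte precursors summed to 4151 ± 2.17, 2102 ± 94.3, 2297 ± 49.1 and 1539 ± 53.2 CPM, and markers of pericytes and smooth muscle to 2188 ± 21.5, 2607 ± 46.1, 994.8 ± 14.2 and 1894 ± 22.4 CPM, in WT and KO at 6 months and then WT and KO at 18 months. The 20 parvalbumin interneuron markers summed to between 611.5 and 671.8 CPM in the group means. Much of that sum came from the potassium channel Kcna1 (124.6 to 340.8 CPM in the group means) and the transcription factor Sox6 (71.7 to 156.6 CPM), while the median of the list was 2.33 to 9.3 CPM over the libraries and 6 of 20 members exceeded 10 CPM in all of them. Pvalb itself (chromosome 15, 78191114 to 78206400 in mm10), which encodes parvalbumin, had 6 reads over the 8 libraries and at most 2 in any of them, too few to test. The 11 markers of GABA neurons summed to 1296 ± 25.1, 780 ± 19.8, 628.4 ± 31.9 and 856.7 ± 15.8 CPM in the same order of groups. Excitatory neuron markers summed to 619.6 ± 0.832, 487.7 ± 12.7, 245.9 ± 0.211 and 318.4 ± 7.92 CPM, and microglial markers to 166.6 ± 9.77, 215.8 ± 2.72, 224.9 ± 10.2 and 96.3 ± 1.94 CPM. All values below are those of this RNA mixture.

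**Figure D1:**
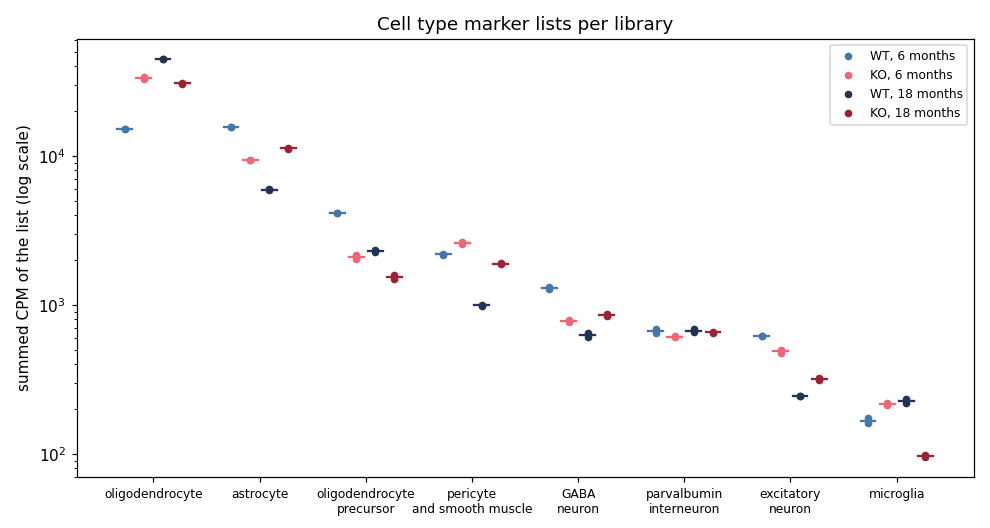
Summed CPM (log scale) of 8 cell type marker lists, with 1 point per library, a short line for the mean of the 2 libraries of a group, and colours for the 4 groups. Oligodendrocyte markers lay between 15200 and 44850 CPM in the group means, while parvalbumin interneuron markers lay between 611.5 and 671.8 CPM.

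The targeted gene was examined first. Dnmt1 (ENSMUSG00000004099, chromosome 9, 20907209 to 20959888 in mm10) was measured at 100.8 ± 4.03 CPM in WT and 76.2 ± 1.39 CPM in KO at 6 months, and at 80.9 ± 0.217 CPM in WT and 75.4 ± 1.64 CPM in KO at 18 months (SD, n = 2). It fell 1.32-fold in KO at 6 months (log2 fold change -0.40, SE 0.0736, edgeR adjusted p = 1e-04). At 18 months the log2 fold change was -0.10 (SE 0.0692, edgeR adjusted p = 0.281). The difference between the ages had an interaction log2 value of 0.30 (SE 0.101, edgeR adjusted p = 0.0202), a call that was lost with DESeq2 (adjusted p = 0.13), without a filter (0.06) and without any of WT replicate 2 at 6 months (0.0831), KO replicate 2 at 6 months (0.0864), WT replicate 1 at 18 months (0.0722), WT replicate 2 at 18 months (0.0614) or KO replicate 2 at 18 months (0.0663). The deletion removes exons 4 and 5 alone, and reads from other exons still count to the gene, so the gene count is a weak check of the genotype. Cre is driven from the parvalbumin locus, and Pvalb had 6 reads over the 8 libraries. Most Dnmt1 reads may therefore come from cells without the deletion. Within WT, Dnmt1 was also lower at 18 months (80.9 CPM) than at 6 months (100.8 CPM). The de novo methyltransferases did not pass the test. Dnmt3a had log2 fold changes of -0.08 (edgeR adjusted p = 0.319) at 6 months and -0.04 (0.622) at 18 months, and Dnmt3b of -0.32 (0.358) and 0.43 (0.183). The list of DNA methylation machinery was not called in either comparison, with 3 members higher and 4 lower of 28 tested at 6 months (camera adjusted p = 0.792) and 6 higher and 6 lower at 18 months (0.84). Adjusted over the list alone, these counts were 3 and 2, and 6 and 7.

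**Figure D2:**
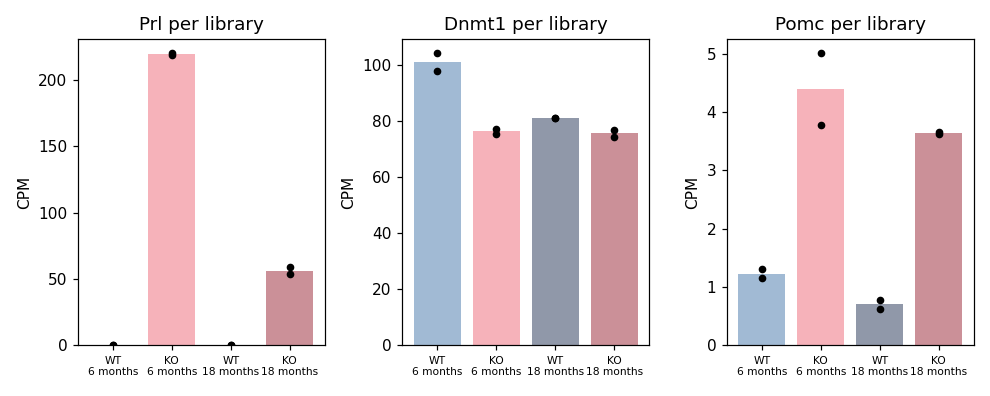
CPM of Prl, Dnmt1 and Pomc per library (points) and as the mean of 2 libraries (bars) in the 4 groups. Prl had 0 reads in the WT libraries and averaged 219.4 CPM in KO at 6 months and 56 CPM in KO at 18 months, while Dnmt1 lay between 75.4 and 100.8 CPM in the group means.

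The comparison of KO with WT at 6 months asked how deletion of Dnmt1 in parvalbumin cells alters their transcriptome in adult animals. In this material, KO libraries held more oligodendrocyte RNA and less astrocyte, precursor and GABA neuron RNA. All 16 oligodendrocyte markers rose, with the myelin genes Mobp at 2189 ± 35.1 against 660.7 ± 32.7 CPM (3.31-fold) and Mbp at 4064 ± 98.2 against 1733 ± 58.8 CPM (2.35-fold; camera adjusted p of the list = 2.29e-25). Of 18 astrocyte markers 17 fell and S100b rose, with the glutamate transporter Slc1a3 at 1017 ± 2.67 against 1976 ± 54.7 CPM (1.94-fold lower) and the glycolytic enzyme Aldoc 2.08-fold lower (list 2.82e-18). Of 12 precursor markers 11 fell and 1 rose, including the growth factor receptor Pdgfra (2.96-fold lower) and the receptor Gpr17 (3.04-fold lower; list 1.68e-12). The GABA-synthesising enzyme Gad1 (ENSMUSG00000070880) fell 8.72-fold, from 128.6 ± 5.39 to 14.7 ± 0.434 CPM (edgeR adjusted p = 7.96e-16), and Gad2 fell 3.1-fold (1.25e-07). In all, 9 of 11 GABA neuron markers fell and 0 rose (camera adjusted p = 5.99e-07).

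Genes of neuronal signalling, and those of perineuronal nets and matrix, moved with these markers. Of 34 neurotransmitter receptor genes 26 fell and 0 rose (camera adjusted p = 8.83e-13), among them the NMDA receptor subunit Grin1 at 22 ± 3.46 against 104.1 ± 5.39 CPM (4.73-fold lower). Of 39 genes of synaptic vesicles and release 28 fell and 3 rose (1.85e-09), including the calcium sensor Syt1 (2.82-fold lower) and the adhesion protein Nrxn3 (4.39-fold lower). Of 38 voltage-gated channel genes 28 fell and 7 rose (8.7e-08), with the T-type calcium channel Cacna1g 3.48-fold lower and the potassium channel Kcna1 2.07-fold higher. Perineuronal net and matrix genes fell in 15 and rose in 3 of 24 cases (6.34e-06), with the proteoglycan Bcan 2.27-fold lower. Tnr belongs to this list and to that of precursors, and the values do not show which cells the matrix RNA came from. These 4 lists, and those of oligodendrocytes, astrocytes, precursors and GABA neurons, kept their calls with an estimated correlation. Somatostatin interneuron markers fell in 5 and rose in 0 of 6 cases (camera adjusted p = 0.00143; adjusted p = 0.143 with an estimated correlation). Markers of parvalbumin interneurons (3 higher and 7 lower of 17, adjusted p = 0.0651), interneurons of caudal origin (2 and 4 of 12, 0.237) and excitatory neurons (1 and 8 of 18, 0.113) were not called as lists.

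Other cell types and cell functions were tested as lists too. All 6 red blood cell genes tested rose (camera adjusted p = 0.000154; adjusted p = 0.0537 with an estimated correlation), with Hbb-bt 6.69-fold higher. Blood leukocyte genes rose in 5 and fell in 0 of 10 cases (0.00618; adjusted p = 0.0998 with an estimated correlation). Among them were the neutrophil genes S100a8 with 225 reads against 1 (ratio 161, 95% interval 28.6 to 6380), Ngp with 185 reads against 3 (44.1, 14.9 to 216) and S100a9 (31.5-fold). Markers of pericytes and smooth muscle rose in 6 and fell in 1 of 12 cases (0.0032; adjusted p = 0.0998 with an estimated correlation). Fibroblast markers fell in 6 and rose in 1 of 9 cases (0.0451; adjusted p = 0.188 with an estimated correlation), a call also lost without KO replicate 2 (0.0678) or WT replicate 2 (0.0582). Microglial markers were higher in 4 and lower in 0 of 18 cases (0.0507). All 7 mitochondrially encoded genes tested rose (6.88e-08; adjusted p = 0.146 with an estimated correlation), with mt-Co1 1.7-fold higher. Genes of clathrin endocytosis and endosomes rose in 29 and fell in 10 of 61 cases (0.0032; adjusted p = 0.102 with an estimated correlation), autophagy genes in 21 and 4 of 48 (0.0118; adjusted p = 0.0956 with an estimated correlation) and proteasome and ubiquitin genes in 15 and 2 of 59 (0.0204; adjusted p = 0.123 with an estimated correlation). Immediate early and dissociation response genes fell in 10 and rose in 1 of 23 cases (0.0164; adjusted p = 0.201 with an estimated correlation), a call also lost without WT replicate 1 (0.0832). Adjusted over the list alone, the counts at 6 months were the same except for GABA neurons (10 lower), pericytes (7 higher), excitatory neurons (2 higher), microglia (3 higher), receptors (27 lower), synaptic vesicles (5 higher and 30 lower), endocytosis (30 and 11), autophagy (22 and 4) and proteasome (14 and 2).

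The single gene farthest from its WT level was Prl (ENSMUSG00000021342, chromosome 13, 27057570 to 27065205), which encodes the pituitary hormone prolactin. It had 1910 and 1843 reads in KO and 0 in WT at 6 months, at least 894-fold higher against a floor of 3 reads over the group. The next largest increases outside blood genes were the Y RNAs Rny1 (18.1-fold) and Rny3 (12.2-fold) and mt-Rnr2 (6.63-fold), all with copies that can share reads. The largest decreases were of Cytl1, a secreted cytokine-like protein, with 177 reads in WT and 1 in KO (ratio 248, 95% interval 43.9 to 9830), and of the metalloprotease Adamts19 with 161 reads against 3 (75.1, 25.2 to 368). The axonemal dynein Dnah11 (30-fold), the Wnt co-receptor Lgr5 (21-fold), Ablim3 (15.4-fold), the synaptotagmin Syt10 (14.1-fold), Cntnap4 (13.1-fold) and Cpne4 (11.2-fold) were lower as well. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3491 genes were higher and 3576 lower in KO, 7067 of 18205 tested, and 869 and 1071 of them by at least 2-fold. If the libraries of a group come from 1 pool, as was assumed here, all of these differences set 1 WT pool against 1 KO pool, and the WT libraries of this age were those that stood apart.

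At 18 months the same genotype comparison gave another picture, with astrocyte and pericyte genes higher in KO and oligodendrocyte, precursor and microglial genes lower. Of 18 astrocyte markers 16 rose and S100b fell (camera adjusted p = 1.39e-21), with the glutamate transporter Slc1a2 at 4642 ± 112 against 2131 ± 8.2 CPM (2.18-fold) and the receptor Fgfr3 at 592.4 ± 10.8 against 245.7 ± 15.2 CPM (2.41-fold). Of 12 pericyte and smooth muscle markers 10 rose and 0 fell (1.07e-09), including the channel subunit Abcc9 (2.44-fold) and the signalling regulator Rgs5 (2.14-fold). All 16 oligodendrocyte markers fell (1.39e-21), with Opalin 1.98-fold and Mal 1.8-fold lower. All 12 precursor markers fell (2.57e-11), with Gpr17 1.84-fold and Pdgfra 1.6-fold lower. Of 18 microglial markers 16 fell and 0 rose (7.14e-10), among them the fractalkine receptor Cx3cr1 at 8.63 against 22.8 CPM (2.65-fold lower), the colony-stimulating factor receptor Csf1r (2.26-fold), the cathepsin Ctss (3.38-fold), Selplg (3.49-fold) and the complement gene C1qa (2.99-fold). These 5 lists kept their calls with an estimated correlation. The neuronal lists were not called, with adjusted p = 0.84 for GABA neurons (2 higher and 2 lower of 11), 0.878 for parvalbumin (5 and 3 of 17), 0.27 for somatostatin (0 and 2 of 6) and 0.703 for excitatory neurons (4 and 6 of 18). Gad1 fell 1.98-fold (edgeR adjusted p = 1.44e-05), at 6.46 ± 0.588 against 12.6 ± 1.73 CPM, and Gad2 fell 2.4-fold (edgeR adjusted p = 0.0031).

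Several lists of cell functions were lower in KO at 18 months, as was the oligodendrocyte list. Summed CPM of proteasome, chaperone, lysosome, autophagy and endocytosis lists was lowest in WT at 6 months and highest in WT at 18 months. The oligodendrocyte markers had the same lowest and highest groups. Endocytosis genes summed to 6368 (WT) and 7437 (KO) CPM at 6 months, and 8872 (WT) and 7430 (KO) at 18 months. A change within cells cannot be told here from a different mix of cells. Proteasome and ubiquitin genes fell in 31 and rose in 0 of 59 cases (camera adjusted p = 1.4e-06), with the ATPase subunit Psmc3 1.45-fold lower. Chaperones fell in 31 and rose in 6 of 57 cases (6.18e-08), with the small heat shock protein Cryab 1.66-fold lower. Autophagy genes fell in 17 and rose in 0 of 48 cases (0.000388), and genes of endocytosis and endosomes fell in 37 and rose in 4 of 61 (1.22e-09). These 4 lists kept their calls with an estimated correlation. Lysosomal genes fell in 33 and rose in 3 of 51 cases (6.34e-09; adjusted p = 0.0859 with an estimated correlation), with Lamp1 1.48-fold lower. Nuclear genes of the respiratory chain fell in 51 and rose in 2 of 76 cases (5.47e-11; adjusted p = 0.0598 with an estimated correlation), with Cox4i1 1.57-fold lower. All 7 mitochondrially encoded genes fell (9.84e-08; adjusted p = 0.156 with an estimated correlation), with mt-Co1 1.75-fold lower. Cytosolic ribosomal protein genes fell in 32 and rose in 0 of 72 cases (4.17e-06; adjusted p = 0.156 with an estimated correlation), with Rpl4 1.75-fold lower. Synaptic vesicle genes fell in 19 and rose in 4 of 39 cases (0.00429; adjusted p = 0.0796 with an estimated correlation). Red blood cell genes fell in 4 and rose in 0 of 6 cases (0.00882; adjusted p = 0.105 with an estimated correlation), with Hbb-bs 3.14-fold lower. Genes of cholesterol synthesis rose in 8 and fell in 0 of 20 cases (0.00429; adjusted p = 0.0796 with an estimated correlation). Adjusted over the list alone, the counts at 18 months were the same except for microglia (17 lower), pericytes (10 and 1), GABA neurons (2 and 4), proteasome (1 and 32), endocytosis (4 and 40), synaptic vesicles (4 and 22), respiratory chain (3 and 54), ribosomal proteins (34 lower) and cholesterol synthesis (10 higher).

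Prl had 699 and 680 reads in KO and 0 in WT at 18 months, at least 390-fold higher against the same floor. The next largest increases were the transporter Slco4a1 (5.1-fold), Emx2os (3.42-fold), an antisense transcript of Emx2 whose reads may be shared with that gene, Greb1 (3.3-fold), the growth factor Hgf (3.08-fold), the long non-coding RNA Rmst (2.99-fold), the transcription factor Tfcp2l1 (2.99-fold) and the receptor Lgr6 (2.9-fold). The largest decreases besides microglial and haemoglobin genes were Mir6236 (5.59-fold, 74.9 ± 61.5 against 408.3 ± 322 CPM) and Lars2 (4.02-fold, 40.1 ± 15.6 against 156.3 ± 99.3 CPM). Both can take rRNA reads and varied widely between the libraries of a group. Next were the gene labelled Zfp469 (3.03-fold), which the annotation used here classes as a long non-coding RNA, and the zinc finger gene Sp7 (2.99-fold). By edgeR's quasi-likelihood test 2679 genes were higher and 3165 lower in KO, 5844 in all, and 713 and 267 by at least 2-fold. The total was 3737 without WT replicate 2 and 3847 with DESeq2.

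**Figure D3:**
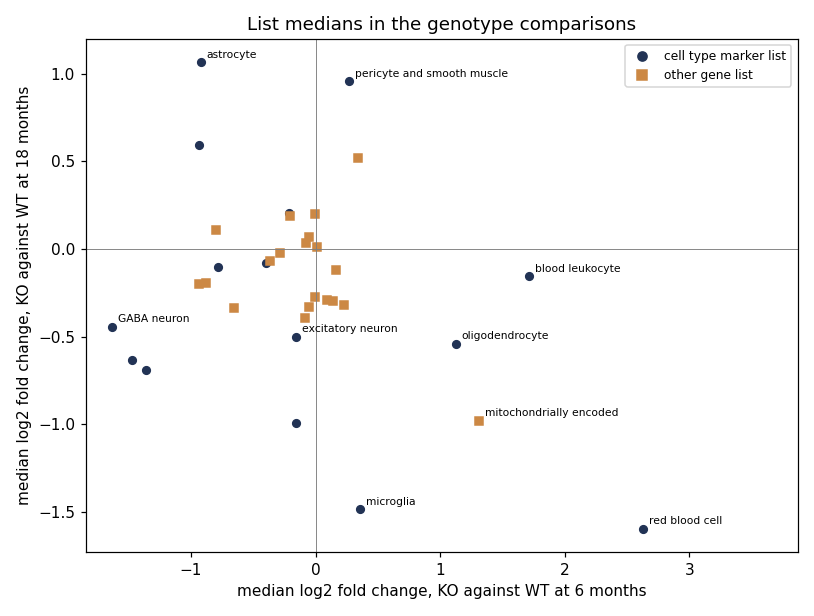
Median log2 fold change of each gene list for KO against WT at 6 months (horizontal axis) and at 18 months (vertical axis), with circles for cell type marker lists and squares for other lists. The oligodendrocyte list lay at 1.12 and -0.54 and the astrocyte list at -0.92 and 1.07, in opposite quadrants.

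Whether the genotype difference itself depended on age was tested by the interaction. Its values include the WT libraries of 6 months, which stood apart from all others, and any difference between single pools. The 5 genes with the smallest adjusted p in each direction are named first. Trim9 (log2 2.26), the Notch modifier Lfng (2.76), Fgfr3 (2.32), Slc1a3 (1.97) and the thyroid hormone transporter Slco1c1 (2.27) went from lower in KO at 6 months to higher in KO at 18 months. The lipocalin Apod (-2.54), Mobp (-2.26), the ferritin chain Fth1 (-2.85), Mal (-1.94) and Mbp (-1.81) did the opposite. Of the astrocyte list 17 of 18 members had a higher and S100b a lower KO to WT ratio at 18 months (camera adjusted p = 1.2e-22), all 16 oligodendrocyte markers a lower one (1.78e-25), and 16 of 18 microglial markers a lower one with 0 higher (5.47e-07). The ratio was lower for 36 and higher for 1 of 59 proteasome genes (1.26e-05), lower for 37 and higher for 6 of 61 endocytosis genes (3.12e-07), and higher for 14 and lower for 2 of 24 perineuronal net genes (3.54e-05). These 6 lists kept their calls with an estimated correlation.

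A further 15 lists had an interaction with the preset correlation and not with an estimated one. Precursor markers had a higher ratio at 18 months for 10 and a lower one for 1 of 12 members (adjusted p = 0.147 with an estimated correlation), pericyte markers for 7 and 0 of 12 (adjusted p = 0.097 with an estimated correlation), fibroblast markers for 7 and 1 of 9 (adjusted p = 0.147 with an estimated correlation) and GABA neuron markers for 4 and 0 of 11 (adjusted p = 0.112 with an estimated correlation). Red blood cell genes had a lower ratio in 6 of 6 cases (adjusted p = 0.0568 with an estimated correlation). Leukocyte genes had a lower one in 5 of 10 (adjusted p = 0.147 with an estimated correlation), a call also lost without KO replicate 1 (0.0675) or 2 (0.0806) at 18 months or WT replicate 2 at 6 months (0.0508). Receptors were higher in 17 and lower in 1 of 34 cases (adjusted p = 0.0568 with an estimated correlation) and channels higher in 17 and lower in 6 of 38 (adjusted p = 0.132 with an estimated correlation). Synaptic vesicle genes were higher in 15 and lower in 8 of 39 (adjusted p = 0.147 with an estimated correlation), a call also lost without KO replicate 2 at 18 months (0.053). Lower ratios were found for 7 of 7 mitochondrially encoded genes (adjusted p = 0.141 with an estimated correlation), 30 of 51 lysosomal genes with 6 higher (adjusted p = 0.147 with an estimated correlation), 26 of 48 autophagy genes with 2 higher (adjusted p = 0.0515 with an estimated correlation), 21 of 57 chaperones with 7 higher (adjusted p = 0.133 with an estimated correlation) and 27 of 76 respiratory chain genes with 3 higher (adjusted p = 0.26 with an estimated correlation). Ribosomal protein genes had a lower ratio in 24 and a higher one in 4 of 72 cases (adjusted p = 0.359 with an estimated correlation), a call also lost without WT replicate 2 at 18 months (0.0744). Adjusted over the list alone, the counts of the interaction were the same except for channels (20 and 7), perineuronal net (15 and 3), proteasome (1 and 37), endocytosis (7 and 41) and autophagy (4 and 26).

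In all, 7126 genes had an interaction by edgeR's quasi-likelihood test, 3358 with a higher and 3768 with a lower ratio at 18 months, and 3344 by at least 2-fold. The genotype calls at the 2 ages shared 293 genes higher in both, against 513.7 for independent lists, and 498 lower in both, against 621.7. They held 2599 genes called in opposite directions, against 1133.2. Among calls of at least 2-fold, 79 genes were lower in both, against 15.7 for independent lists, 21 higher in both, against 34, and 137 opposite, against 54.7. Across genes, which are not independent replicates, the log2 fold changes at the 2 ages had Pearson's r of -0.063 and Spearman's rho of -0.157.

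The additive model asked which genes differed between KO and WT on average over the ages, which does not require a difference at each age. By edgeR's quasi-likelihood test 126 were higher and 440 lower, 566 in all. Besides Prl (adjusted p = 9.3e-05), the genes with the smallest adjusted p among those higher in KO were the calcium pump Atp2a3 (log2 0.99, 0.00115), the processed pseudogene Gm19963, whose reads may be shared with its parent gene (1.10, 0.00392), the hormone precursor Pomc (2.09, 0.00445) and the basement membrane gene Nid1 (0.71, 0.00501). Among those lower in KO they were the axonal spectrin Sptbn4 (-1.51, 0.000581), Cytl1 (0.000581), the postsynaptic scaffold Shank1 (-1.29, 0.000581), Agap2 (-1.47, 0.000584) and the NMDA receptor subunit Grin2a (-1.62, 0.000672). Gad1 fell by 2.15 on the log2 scale (0.0256) and Gad2 by 1.51 (0.00513), while the value was -0.25 for Dnmt1 (0.195), -0.06 for Dnmt3a (0.777) and 0.08 for Dnmt3b (0.898). The call of Cytl1 rests on 6 months, since it had 2 reads in WT and 0 in KO at 18 months. The call of Gad1 was lost without KO replicate 1 (0.114) or 2 (0.119) or WT replicate 1 (0.0696) or 2 (0.07) of 6 months. Leaving out any of the 8 libraries in turn gave totals of 146 to 376, and the total was 971 with DESeq2 and 1, Prl, when libraries were summed to 4 pools. The fit of 4 sums leaves few residual degrees of freedom and has little power. Sptbn4 (log2 -1.49) and Grin2a (-1.60) had folds there close to those above but did not pass. Without a filter the total was 1458 (688 higher and 770 lower), and for the average of the genotype contrasts 5054 (2731 higher and 2323 lower). The excess of lower genes thus depends on the fit, being small in the first of these and absent in the second. It remained with limma-voom (21.5% of calls higher), relative log expression scaling (21.8%), the strict filter (26.6%), upper-quartile scaling (28.1%) and DESeq2 (28.7%). Around Dnmt1 no difference in the share of called genes passed the test at the set distance, with 36.1% called within 20 Mb and 38.9% elsewhere at 6 months (two-sided Fisher's exact test, p = 0.443), 34.2% and 32.1% at 18 months (p = 0.512), and 4.6% and 3.1% across both ages (p = 0.234). Within 40 Mb at 18 months it was higher, at 37.5% against 32% (two-sided Fisher's exact test, p = 0.0143).

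The comparison of 18 with 6 months in WT asked how the sorted cells change with age in control animals. Oligodendrocyte RNA was higher and astrocyte, neuronal and pericyte RNA lower at 18 months. All 16 oligodendrocyte markers rose (camera adjusted p = 1.59e-18), with Mobp 3.61-fold and Mbp 3.42-fold higher. Of 18 astrocyte markers 17 fell and S100b rose (1.02e-14), with Fgfr3 3.95-fold and Slc1a3 3.22-fold lower. All 11 GABA neuron markers fell (8.4e-06), with Gad1 10-fold lower, and of 18 excitatory neuron markers 16 fell and 0 rose (8.4e-06). All 12 pericyte and smooth muscle markers fell (4.79e-07), with the smooth muscle actin Acta2 at 74.9 ± 1.5 against 279 ± 16.1 CPM (3.72-fold) and the myosin Myh11 3.51-fold lower. Genes of synaptic vesicles (33 lower and 4 higher of 39, 1.05e-10), channels (30 and 5 of 38, 1.65e-07), receptors (28 and 2 of 34, 6.03e-09) and perineuronal nets (16 and 1 of 24, 2.2e-06) fell, among them Grin1 (19.9-fold), Syt1 (9.84-fold), Grin2b (8.19-fold) and the priming factor Unc13a (6.44-fold). Proteasome and ubiquitin genes rose in 39 and fell in 1 of 59 cases (1.06e-05), with Psmc2 1.96-fold higher. These 10 lists kept their calls with an estimated correlation. The libraries of WT at 6 months, which stood apart from all others, enter every one of these values.

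Further lists changed in WT with the preset correlation alone. Precursor markers fell in 11 and rose in 1 of 12 cases (adjusted p = 0.073 with an estimated correlation), fibroblast markers in 8 and 1 of 9 (adjusted p = 0.127 with an estimated correlation), somatostatin markers in 6 and 0 of 6 (adjusted p = 0.167 with an estimated correlation) and markers of interneurons of caudal origin in 9 and 1 of 12 (adjusted p = 0.281 with an estimated correlation). Parvalbumin interneuron markers fell in 12 and rose in 3 of 17 cases (adjusted p = 0.298 with an estimated correlation), a call also lost without WT replicate 2 at 18 months (0.0575). Immediate early and dissociation response genes fell in 20 and rose in 1 of 23 cases (adjusted p = 0.073 with an estimated correlation), including Junb (3.05-fold) and Fos (3-fold). Genes of endocytosis and endosomes rose in 40 and fell in 11 of 61 cases (adjusted p = 0.0624 with an estimated correlation), autophagy genes in 28 and 8 of 48 (adjusted p = 0.073 with an estimated correlation), lysosomal genes in 31 and 8 of 51 (adjusted p = 0.225 with an estimated correlation) and chaperones in 29 and 9 of 57 (adjusted p = 0.0894 with an estimated correlation). Examples were Dnajb2 (2.3-fold), Vmp1 (2.11-fold) and Lamp1 (2.03-fold). All 7 mitochondrially encoded genes rose (adjusted p = 0.277 with an estimated correlation). Adjusted over the list alone, the counts were the same except for proteasome (40 and 2) and receptors (4 higher and 28 lower).

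Among single genes in WT, the complement gene C4b rose from 39.7 ± 0.669 to 348.2 ± 14.3 CPM (8.78-fold, edgeR adjusted p = 1.47e-19). Rny1 (20.5-fold), Rny3 (9.72-fold), the sulphate transporter Slc13a1 (9.12-fold), the ubiquitin ligase Trim59 (7.99-fold), Apbb1ip (7.67-fold), the channel protein Clic5 (7.19-fold) and the receptor Adgrg2 (7.17-fold) rose as well. The largest decreases were of Cytl1, with 177 reads at 6 and 2 at 18 months (ratio 152, 95% interval 41.4 to 1260), Cntnap4 (58.4-fold), Dnah11 (57.2-fold), the stress hormone receptor Crhr1 (57-fold), the activity-regulated factor Npas4 (44.5-fold), Actn2 (39.1-fold), Col6a1 (38.9-fold) and the potassium channel Kcnj4 (36.4-fold). The maternally expressed non-coding RNA Meg3 fell 15.2-fold. By edgeR's quasi-likelihood test 5133 genes were higher and 5615 lower at 18 months, 10748 in all, and 1753 and 3346 by at least 2-fold.

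In KO the comparison of 18 with 6 months showed lower excitatory neuron, microglial, pericyte and blood cell RNA at the older age. Of 18 excitatory neuron markers 14 fell and 1 rose (camera adjusted p = 1.49e-07), with the kinase Camk2a at 17.3 ± 2.98 against 115.1 ± 3.23 CPM (6.68-fold lower) and the vesicular glutamate transporter Slc17a7 7.98-fold lower. Of 18 microglial markers 16 fell and 0 rose (9.28e-10), with Cx3cr1 2.62-fold and Csf1r 2.59-fold lower. Of 12 pericyte and smooth muscle markers 8 fell and 0 rose (1.68e-06), with Acta2 3.62-fold and Myh11 3.24-fold lower. All 6 red blood cell genes fell (1.3e-06), with Hbb-bt 14.7-fold lower, and 9 of 10 leukocyte genes fell (1.01e-07), with S100a8 44.3-fold, S100a9 40.2-fold and Ngp 20.1-fold lower. Immediate early and dissociation response genes fell in 21 and rose in 0 of 23 cases (7.49e-12), with Egr1 6.48-fold and Fos 2.41-fold lower. Synaptic vesicle genes fell in 30 and rose in 2 of 39 cases (7.91e-15), with Syt1 7.4-fold and the active zone protein Bsn 5.98-fold lower, and channels fell in 24 and rose in 5 of 38 (1.04e-07). Clustered protocadherin beta genes, cell adhesion genes whose similar sequences can share reads, rose in 14 and fell in 0 of 21 cases (1.36e-07), with Pcdhb11 4.53-fold and Pcdhb14 1.87-fold higher. These 9 lists kept their calls with an estimated correlation.

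The GABA neuron markers fell in 8 and rose in 1 of 11 cases in KO with age (camera adjusted p = 0.00145; adjusted p = 0.0732 with an estimated correlation), with Gad1 2.27-fold lower. Somatostatin markers fell in 4 and rose in 0 of 6 (adjusted p = 0.218 with an estimated correlation), markers of interneurons of caudal origin in 7 and 0 of 12 (adjusted p = 0.218 with an estimated correlation), receptors in 21 and 6 of 34 (adjusted p = 0.103 with an estimated correlation) and perineuronal net genes in 12 and 2 of 24 (adjusted p = 0.0919 with an estimated correlation). Astrocyte markers rose in 12 and fell in 0 of 18 cases (adjusted p = 0.103 with an estimated correlation), with Gjb6 1.46-fold and Slc1a2 1.25-fold higher. Precursor markers fell in 10 and rose in 0 of 12 (adjusted p = 0.0732 with an estimated correlation). Oligodendrocyte markers fell in 6 and rose in 3 of 16 cases (adjusted p = 0.103 with an estimated correlation), a call also lost without KO replicate 1 at 6 months (0.0606). All 7 mitochondrially encoded genes fell (adjusted p = 0.103 with an estimated correlation), nuclear respiratory chain genes fell in 29 and rose in 3 of 76 cases (adjusted p = 0.177 with an estimated correlation) and ribosomal protein genes in 18 and 1 of 72 (adjusted p = 0.298 with an estimated correlation). Adjusted over the list alone, the counts were the same except for excitatory neurons (2 higher), microglia (17 lower), immediate early genes (22 lower), synaptic vesicles (31 lower), channels (25 lower), protocadherins (17 higher), somatostatin (5 lower), caudal interneurons (1 higher), receptors (7 higher), perineuronal nets (13 lower), astrocytes (1 lower), oligodendrocytes (4 and 7), respiratory chain (30 lower) and ribosomal proteins (17 lower).

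Single genes that rose most in KO with age included the cadherin Cdh8 (4.6-fold), Clic5 (4.6-fold), the transcription cofactor Eya4 (3.39-fold), the matrix gene Svep1 (2.95-fold), Slc7a15 (2.75-fold), the bradykinin receptor Bdkrb2 (2.59-fold) and Cyp3a13 (2.42-fold). Those that fell most, besides the leukocyte and haemoglobin genes, were Meg3 (15.6-fold), Col6a1 (14.1-fold), the postsynaptic protein Dlgap2 (11.1-fold) and the neuronal splicing factor Rbfox3 (10.2-fold). By edgeR's quasi-likelihood test 2512 genes were higher and 3263 lower, 5775 in all, and 269 and 1190 by at least 2-fold. The total was 3540 without KO replicate 1 at 18 months, 3255 without KO replicate 2 at 6 months and 3477 with DESeq2. The age calls in WT and KO shared 1430 genes higher in both, against 708.3 for independent lists, and 2000 lower in both, against 1006.4, while 1013 were called in opposite directions, against 1694.8. Across genes the log2 fold changes had Pearson's r of 0.479 and Spearman's rho of 0.387, and their median absolute size was 0.6 in WT and 0.28 in KO.

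**Figure D4:**
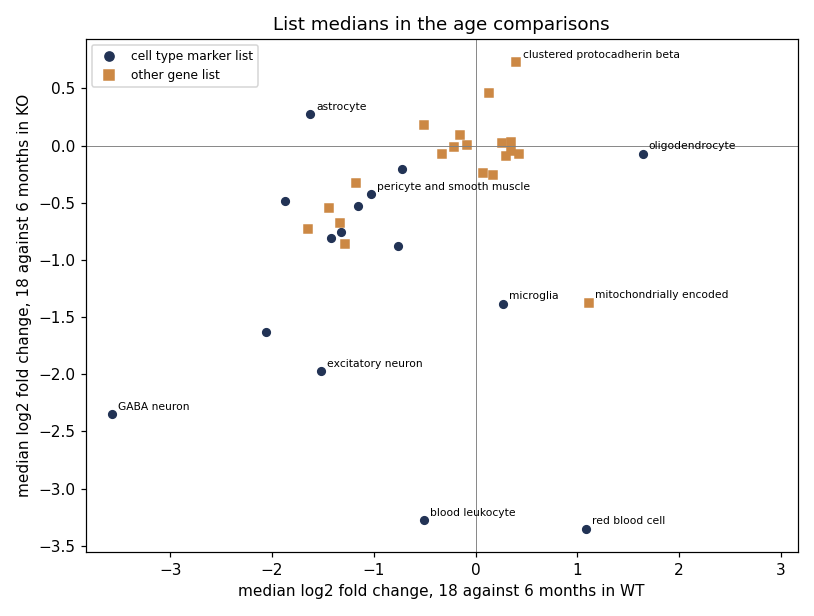
Median log2 fold change of each gene list for 18 against 6 months in WT (horizontal axis) and in KO (vertical axis), with circles for cell type marker lists and squares for other lists. GABA neuron and excitatory neuron lists were below 0 in both genotypes, and the red blood cell list lay at 1.09 in WT and -3.35 in KO.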

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

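Of the tests in this part, those on glial and GABA neuron lists, Prl, the spread within lists and the 18-month libraries alone were chosen after the results were seen; the test on depth was set before. The results singled out here are differences between the ages in the ratio of KO to WT, tested by the interaction. There were 7126 such genes. Those with the smallest adjusted p in each direction were Trim9 (log2 2.26), Lfng (2.76), Fgfr3 (2.32), Slc1a3 (1.97) and Slco1c1 (2.27), with a higher ratio of KO to WT at 18 than at 6 months, and Apod (-2.54), Mobp (-2.26), Fth1 (-2.85), Mal (-1.94) and Mbp (-1.81) with a lower one. Dnmt1 had an interaction of 0.30, a call lost with DESeq2 (0.13), without a filter (0.06) and in 5 of the fits with 1 library left out (0.0614 to 0.0864).

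The RNA of all 8 libraries was richer in glial than in interneuron transcripts. In the library with the lowest ratio, the median CPM of the oligodendrocyte list was still 20.3 times that of the GABA neuron list, and Mbp reached 1733 CPM in the group where it was lowest. The marker lists share 0 members. A loss of Pvalb reads alone is argued against by the other interneuron genes: the GABA neuron list reached at most 0.0493 of the oligodendrocyte median in any library. Glial RNA in the sorted material is consistent with these values, and so are count files that belong to another cell sort, which the counts cannot exclude and which would change the meaning of all values. Sorting for tdTomato would be meant to remove glial cells, and whole glial cells and free glial RNA cannot be separated in bulk counts. Whether the RNA of any parvalbumin cells differed by genotype stays open.

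Prl had 5132 reads in the 4 KO libraries and 0 in the 4 WT libraries, and it was the 1 gene with at least 20 reads in every KO library and at most 3 in all WT libraries; 0 genes had the reverse pattern. Pituitary tissue is argued against by growth hormone, Gh, with 1 read in the KO libraries, and reads shared with the other 25 genes of the prolactin family by the 3 reads that these held in KO. For lactotroph cells alone, 1 gene besides Prl, Pomc, was called higher across both ages among the 9 genes of the pituitary list that were tested, Chga and Pcsk2 were lower, and the pituitary factor Pou1f1 had 21 reads in KO against 2 in WT. A few such cells in the KO pools, or transcription of Prl in the sorted cells of KO mice, may both account for this and cannot be told apart with 1 pool per group, as assumed here.

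Oligodendrocyte and astrocyte genes moved in opposite directions between the genotypes, and the directions turned between 6 and 18 months. The genotype calls of these genes at 18 months do not rest on the WT libraries of 6 months. In a fit of the 4 libraries of 18 months, 33 of the 34 members of both lists were called. That fit leaves out the WT libraries of 6 months and cannot show whether they cause the turn between the ages. The oligodendrocyte markers summed to 15200 CPM in WT and 33670 CPM in KO at 6 months, and to 44850 and 30820 CPM at 18 months. After thinning to the smallest library the smallest of the 4 absolute list medians was 0.562. Thinning keeps the expected ratios of genes with many reads, so this test could not decide on depth. A different mix of glia in the pools predicts 1 shared fold per list. The SD of log2 fold changes over the oligodendrocyte list was 0.223 at 6 and 0.18 at 18 months. These lay at most at percentile 0.14 of 10000 random lists, as a shared fold predicts. Markers regulated together within oligodendrocytes would also have a small spread, so this test cannot tell that from a different mix. The astrocyte list, which was added to the test after its values were seen, lay at percentile 0.63 at 6 months (SD 0.342), as predicted too, but at percentile 50.9 at 18 months, with S100b at -0.41 and Apoe at -0.01 against a median of 1.07. The other astrocyte members lay between 0.79 and 1.27 at 18 months, so S100b and Apoe made the wide SD. S100b moved in the direction of the oligodendrocyte list at both ages. With 1 pool per group, as assumed here, mix, genotype and the difference between single pools cannot be told apart. An effect of Dnmt1 deletion or age stays open.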

How the results depend on the processing

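The fits without rRNA-like genes and without both WT libraries of 6 months were chosen after the data had been seen; all others were set before the data were examined. Over the genes named, 2458 of 2512 alternative values kept their direction and their side of the threshold. Over the called lists 734 of 798 did, and 54 of the 64 lost calls came from the estimated correlation. With a minimum of 2-fold the totals were 1940 (KO against WT at 6 months), 980 (at 18 months), 5099 (age in WT), 1459 (age in KO), 3344 (interaction) and 262 (across both ages), and Dnmt1 at 6 months, at -0.40, no longer passed. DESeq2 called 3847 for KO against WT at 18 months, 3477 for age in KO and 971 across both ages; the cause was not tested. Leaving out 1 library at a time gave 3737 to 4814 for KO against WT at 18 months, 3255 to 4996 for age in KO and 146 to 376 across both ages, with fewer libraries in each fit. Across both ages no filter gave 1458 genes (47.2% higher, against 22.3%), and the cause was not tested. The sum to 4 pools, a fit with few residual degrees of freedom, gave 1 gene (Prl, edgeR adjusted p = 0.00265). The average of the genotype contrasts gave 5054 (54% higher), and its residual leaves out the differences between pools. With the replicate number as a block the count across both ages was 274 (cause not tested), Gad1 there lost its call (0.0706), and no other count moved by more than 1.5 times; deviations of same-numbered libraries correlated at -0.007 to 0.089 between WT at 6 months and the other groups and at 0.223 to 0.366 among those 3 groups. Since not every pair of groups was over 0.1 and the labels name nothing that the numbers share, they were not taken as pairs. Dnmt3a at 18 months, which did not pass, turned from -0.04 to 0.015 without WT replicate 2 and lay between -0.065 and 0.015 over the libraries left out. Dnmt3b across both ages (0.08) lay between -0.071 and 0.209, turning without KO replicate 2 or WT replicate 1 at 18 months (-0.067). Apoe at 18 months (-0.01) was 0.02 with upper-quartile scaling, 0.016 without a filter, 0.026 with the strict filter, and between -0.077 and 0.057 over the libraries left out; neither gene passed in any of these fits. With an estimated correlation the called marker lists were 4 (6 months), 5 (age in WT), 5 (age in KO) and 3 (interaction), and the other lists 4, 4 (18 months), 5, 4 and 3; fry, which does not compare a list with other genes, called 14, 18 and 16 other lists for KO against WT at 6 months, age in WT and age in KO. Around Dnmt1 at 6 months the p was 1 within 5 Mb, 0.472 within 10 Mb and 0.961 within 40 Mb, with the odds ratio on either side of 1, and at 18 months it was 0.0143 within 40 Mb; the cause was not tested. With 2-fold calls the genotype comparisons shared 21 genes higher (34 for independent lists), 79 lower (15.7) and 137 opposite (54.7), so that genes lower in both turned from below to above the independent number. The age comparisons shared 123 (25.9), 861 (218.7) and 42 (164). Without both WT libraries of 6 months 6337 genes were called for KO against WT at 18 months and 6126 for age in KO. With 2 technical libraries per group, depth limits what can be said of Pvalb and other genes with few reads, and the number of pools limits all comparisons.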

Other observations

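Gene groups that could respond to a loss of DNA methylation were not called as lists between the genotypes. Glial markers far outweighed those of interneurons in this RNA, so these lists say little about a loss in parvalbumin cells. Imprinted genes were higher in 12 and lower in 8 of 36 cases in KO at 6 months (camera adjusted p = 0.792; 13 and 10 adjusted over the list alone), and higher in 6 and lower in 5 at 18 months (0.84; 6 and 5). With age, they were higher in 11 and lower in 17 cases in WT (0.478; the same counts over the list alone) and higher in 8 and lower in 13 in KO (0.161; 8 and 15). Of 30 germline genes silenced by promoter methylation, 4 had enough reads to test. In KO 1 was higher at 6 months (0.792; 1 over the list alone) and 2 at 18 months (0.519; 2 higher and 1 lower over the list alone), where the synaptonemal complex gene Sycp2 rose 2.5-fold, at 39.8 ± 1.78 against 16.2 ± 2.64 CPM (edgeR adjusted p = 1.31e-08). Clustered protocadherin beta genes were lower in 6 and higher in 0 of 21 cases in KO at 6 months (0.209) and higher in 3 and lower in 3 at 18 months (0.793), with the same counts adjusted over the list alone. With age that list was called in KO (14 higher and 0 lower, 1.36e-07; 17 and 0 over the list alone) and not in WT (8 higher and 1 lower, 0.0826; the same counts).

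The lists of the interferon response and of the p53 response, and those of 2 further cell types, were likewise not called between the genotypes. Genes of the interferon response and antigen presentation were higher in 1 and lower in 9 of 31 cases in KO at 6 months (camera adjusted p = 0.209; 1 and 8 adjusted over the list alone) and higher in 3 and lower in 4 at 18 months (0.703; 3 and 4). Genes of the p53 response and apoptosis were higher in 8 and lower in 8 of 30 cases at 6 months (0.982; 8 and 9) and higher in 4 and lower in 3 at 18 months (0.839; 4 and 3). Endothelial markers were higher in 3 and lower in 3 of 18 cases at 6 months (0.962; 3 and 3) and higher in 3 and lower in 2 at 18 months (0.703; 3 and 2). Of the ependymal and choroid plexus markers 3 were tested, with 1 higher and 1 lower at 6 months (0.982; 1 and 1) and 1 higher and 2 lower at 18 months (0.35; 1 and 2).

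The additive comparison of KO with WT was repeated on other divisions of the 8 libraries into 4 and 4, a test set before the results were seen. Of 35 divisions 34 could be fitted, and 2 of them, the real one included, called as many genes as the 566 of the real one. These 2 are the only fitted divisions that keep the libraries of each group together, and all others called 0. If the libraries of a group are replicates of 1 pool, the divisions that part them say nothing about chance, and those left are too few to judge it. The highest other count was 3935, several times the real one, for KO at 18 months with WT at 6 months against KO at 6 months with WT at 18 months. That division is the crossing of genotype and age. With 1 pool per group, its count cannot tell an age dependence of the genotype effect from differences between single pools.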
